A study of Mus musculus with 2 samples.

How the data were processed

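RNA of tissue labelled as mouse subcutaneous fat was measured in 2 libraries. The labels number them as biological replicates 1 and 2 of a single group and assign them to separate tissue samples under a shared donor record. Per the labels, the tissue came from C57BL/6J littermates of both sexes at 8 weeks of age, the RNA was over 200 nt long, depleted of ribosomal RNA and selected for polyA tails, synthetic spike-in RNAs were added, and stranded paired reads of 76 nt were sequenced. The name of the program that counted the reads is not given in the sources used here; the columns of the tables are those that RSEM writes. Per the notes deposited beside the tables, reads were aligned to the transcripts of mouse genome build mm10 with GENCODE release M4.

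The deposited gene and transcript tables give an expected count for each feature, in which the authors' program divided reads that match several features among them. They also give deposited TPM values, a relative transcript abundance over all features including spike-ins, and deposited FPKM values, fragments relative to transcript length and library size. The deposited transcript tables give the percent of a gene's TPM that each transcript takes. Reads of near-identical copies are split by the model, so the values of such genes are uncertain. A further pair of deposited tables covers both libraries together on genome build mm9: a junction table with a count of reads and a score per splice junction, and a contig table with a signal level, a score and a number of read bases per transcribed stretch. The score in these deposited tables has no stated definition; it falls as reads increase. The junction names carry a pair of read numbers that sum to the count, and no label ties either number to replicate 1 or replicate 2. The mm9 tables were not joined to the mm10 tables.

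Each gene table held 69691 features: 43346 annotated genes, 26248 tRNA features, which had a count of 0 in both libraries, and 97 spike-in or control sequences, of which 96 were ERCC spike-ins. Gene symbols were matched by identifier for 42462 genes; the 884 others held 0.120% and 0.0762% of the gene counts of replicates 1 and 2. Gene coordinates and transcript names are from GENCODE release M21 on GRCm38, the same build as mm10. Annotated genes without the spike-ins entered all library sizes. Total estimated counts were 54752739 in replicate 1 and 58687668 in replicate 2, so 3 counts of a transcript 1 kb long correspond to about 0.0827 and 0.0701 TPM.

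With a single group there is no comparison between conditions. Levels are given as the mean ± SD of TPM over the 2 libraries (n = 2). TPM values were not scaled with the TMM factors below, so a small SD of TPM does not mean equal scaled counts. For the comparison of the replicates, expected counts were rounded to whole numbers and scaled with TMM factors from edgeR (version 4.0.16, R 4.3.3), which were 1.20 and 0.837. Ratios are replicate 2 over replicate 1, with exact Clopper-Pearson 95% intervals of the split of the 2 counts; these intervals, and the floor of 3 counts used where a count was 0, cover counting error only. A gene was called over 2-fold apart when its mean scaled count was at least 100 and its interval lay wholly above 2 or below 0.5. Lists were compared over members with a mean scaled count of at least 10, and a member is described as over 2-fold higher when its interval lies beyond that bound. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on expression in 20 bins, and lists of at least 4 such members in the outer 2.5% on either side are described as outside the random lists. These percentiles describe the libraries and are no test of a condition. No p-values were computed, because each side of the comparison is 1 library. The common biological coefficient of variation was estimated with edgeR.

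The gene lists and the rule for named genes were fixed before the data were examined: the 10 genes of highest mean TPM outside the mitochondrial genome, the 4 highest members of each list, the 12 highest and 12 lowest replicate ratios among genes with a mean scaled count of at least 100, 15 genes chosen for isoform use, and Ucp1, Lep, Xist and 4 Y genes. Some genes that this rule names are not reported here. Any other gene was chosen after its values were seen. The 38 lists cover adipocyte functions, the other cell types of the fat pad and its surroundings, and general programs. Some genes are in several lists, so a count of lists is not a count of independent results. Of these, 35 had at least 4 members to compare. Older symbols were matched through synonyms; Muc16, Snhg1 and Rn7sl1 were not found. A further 12 lists of other tissues and fat depots were written after the first look at the data.

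Alternatives covered the TPM threshold, FPKM and posterior mean values, DESeq2 (version 1.42.0) size factors, total count and spike-in scaling, count filters, pseudocounts of 0.1 and 1 on TPM, the statistic of the lists, each replicate left out, and score, read and length filters for junctions and contigs. The steps were tested on simulated counts for the 43346 genes, drawn from the means and library sizes of these replicates with 200 genes changed: 100% of the genes raised 8-fold, 99% of the genes lowered to an eighth and 0.704% of unchanged genes passed the 2-fold rule. A simulated coefficient of variation of 0.2 was recovered as 0.252 with the changed genes included. The replicates themselves had a larger coefficient of 0.645. The 0.704% therefore holds for the simulated spread only and does not describe the calls made between these replicates. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for the plots.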

Results

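The transcriptome of tissue labelled as mouse subcutaneous fat, a white adipose depot under the skin, was profiled in 2 libraries. Per the labels, the tissue came from C57BL/6J animals of both sexes at 8 weeks. The series holds a single group. The questions it can answer are which genes the tissue expressed and how far its replicates differed. Replicate 1 had 54752739 estimated counts and replicate 2 had 58687668, of which annotated genes took 53601218 and 57500971.

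A total of 12759 genes reached a TPM of at least 1 in both replicates, and 93.5% of these were protein coding. A further 2003 genes reached it in replicate 1 only and 317 in replicate 2 only. The 10 most abundant genes held 17.9 ± 7.30% of TPM (SD, n = 2) and the 100 most abundant held 40.1 ± 9.04%. Replicate 2 was the more concentrated library, with 23.1% in its first 10 genes against 12.8% in replicate 1. The 13 mitochondrial mRNAs took 11.1 ± 6.50% of TPM (SD, n = 2), 6.51% in replicate 1 and 15.7% in replicate 2. By TPM, mt-Atp8, a short gene with 1410 and 5340 counts, came before mt-Co1, with 779858 and 2297625, mt-Co3 and mt-Cytb. In replicates 1 and 2, mt-Atp8 held 17961.5 and 59486.9 of the 65108.6 and 157054 TPM of the 13 mRNAs. These TPM shares, that of the first 10 genes included, thus lean on a gene with few counts. Without mitochondrial genes the 10 most abundant held 13.4% on average. Reads shared with nuclear copies, described below, add to the uncertainty. All mitochondrial genes together took 3.04% and 7.14% of gene counts.

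Among nuclear genes, Cfd, which encodes the adipokine adipsin (ENSMUSG00000061780.5, GRCm38 chromosome 10, 79890853 to 79892655), averaged 14550 ± 2805 TPM (SD, n = 2). The carbonic anhydrase gene Car3 averaged 11183.5 ± 9266, the fatty acid synthase gene Fasn 8639 ± 3471 and the desaturase gene Scd1 7693 ± 2514. The other leading features were Gm29216 at 20528 ± 13328, Gm10222 at 11211 ± 5831 and Gm28437 at 8074 ± 6898, and 3 small noncoding RNA genes, Rn7sk at 18350 ± 18594 and Rn7s1 and Rn7s2 at 6227 ± 1867 each. Gm29216, Gm10222 and Gm28437 are annotated as unprocessed pseudogenes on chromosome 1, where a nuclear copy of mitochondrial sequence lies. Rn7s1 and Rn7s2 had identical values, so the division of reads behind these 5 values is uncertain.

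Adipocyte functions were all represented. All 18 members of the white adipocyte list had a TPM of at least 1 in both replicates, with Fabp4, a fatty acid carrier, at 4307 ± 3417 TPM (SD, n = 2) and the lipoprotein lipase gene Lpl at 3269 ± 2960. All 19 genes of fatty acid and triglyceride synthesis and all 15 of lipolysis also passed, including Dgat2 (2625 ± 1556), Thrsp (1878 ± 565), Pnpla2 (1767 ± 982), Plin1 (903 ± 485), Lipe (746 ± 517) and Adrb3 (679 ± 277). In the adipokine list 21 of 22 genes passed, with Apoe at 2605 ± 222, adiponectin (Adipoq) at 2294 ± 1834, resistin (Retn) at 1524 ± 920 and leptin (Lep) at 523 ± 614 TPM. On GRCm38, Adipoq lies on chromosome 16, 23146536 to 23158028, and Lep on chromosome 6, 29060220 to 29073877. The insulin and glucose uptake list passed in full (16 of 16), with Cav1 at 2730 ± 1474, the insulin-responsive glucose transporter Slc2a4 at 209 ± 59.1, Akt2 at 197 ± 52.1 and Akt1 at 134 ± 71.0. The SD of Lep exceeded its mean, so 2 libraries do not fix its level.

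Transcripts of heat-producing fat were present at lower levels. Ucp1, the uncoupling protein of brown and beige adipocytes, averaged 230 ± 142 TPM (SD, n = 2), Cox8b 229 ± 148, Cidea 104 ± 70.3 and Cox7a1 57.0 ± 42.4, and 14 of the 16 genes of this list passed a TPM of 1 in both libraries. Of the 5 genes listed as classical brown markers 3 passed, Pdk4 at 59.5 ± 47.5, Mpzl2 at 5.50 ± 4.83 and Eva1a at 3.71 ± 3.04, while Lhx8 had 1 and 0 counts in replicates 1 and 2. Of the 8 beige markers 4 passed. Slc27a1 was at 301 ± 19.1, Epsti1 at 5.37 ± 4.20 and Hoxc9 at 3.71 ± 1.19, while Cited1 (2.35 ± 2.85) was below a TPM of 1 in replicate 2. All 25 nuclear genes of the respiratory chain passed, with Atp5b at 3158 ± 720 and Cox6a1 at 2098 ± 282, Atp5a1 at 1399 ± 90.0 and Cox4i1 at 1084 ± 52.8.

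Genes of stromal and vascular cells were as broadly represented, and whether all these transcripts came from the fat pad was not tested. All 24 matrix genes and all 15 genes of progenitors and fibroblasts passed in both libraries, including Sparc at 5999 ± 2957 TPM (SD, n = 2), Gsn at 3980 ± 2805, Mgp at 1267 ± 93.8, Col6a2 at 871 ± 542, Col6a1 at 831 ± 463, Dcn at 810 ± 302, Mfap5 at 333 ± 18.9 and Ly6a at 285 ± 2.13. The endothelial list passed in full (15 of 15), with Egfl7 at 513 ± 202 and Gpihbp1, which anchors lipoprotein lipase to capillaries, at 435 ± 411. So did the 14 genes of smooth muscle and pericytes, with Acta2 at 1998 ± 2219, Tagln at 543 ± 567 and Mcam at 221 ± 77.7. The replicates were unlike here, with Acta2 at 3567 TPM in replicate 1 and 428 in replicate 2. Blood was visible as haemoglobin, Hba-a2 at 1531 ± 376, Hbb-bs at 1164 ± 168, Hba-a1 at 584 ± 152 and Hbb-bt at 132 ± 16.2. In nerve, 7 of 11 genes passed, with Pmp22 at 164 ± 12.9 and S100b at 8.63 ± 9.60.

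Of immune cells, macrophages and antigen presentation gave the highest values. In the macrophage list 15 of 16 genes passed, with Retnla at 532 ± 238 TPM (SD, n = 2), Lyz2 at 545 and 455 TPM in replicates 1 and 2, C1qb at 240 ± 77.8 and C1qc at 204 ± 58.9. All 9 class II genes passed, with Cd74 at 1120 ± 303, H2-Ab1 at 746 ± 347, H2-Aa at 460 ± 132 and H2-Eb1 at 259 ± 83.3. All 15 interferon response genes passed, led by Ifi27l2a (2518 ± 214), Bst2 (372 ± 250) and Irf7 (68.4 ± 18.7). Lymphocyte genes were low: 3 of 15 T cell genes and 4 of 15 B cell genes passed, with Ccr7 at 2.29 ± 0.00707 and Cd79b at 3.33 ± 0.827. Immunoglobulin M (Ighm) was the exception at 476 ± 553. Of the 10 genes of lymph node stroma 5 passed, with the chemokine gene Ccl21a, which can share reads with close copies, at 84.1 ± 98.1 (153 and 14.7 in replicates 1 and 2), Fcna at 14.7 ± 1.27, Lyve1 at 12.8 ± 6.14 and Il33 at 3.63 ± 0.276.

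Genes of the surroundings of the fat pad were low or uneven. In skeletal muscle 5 of 20 genes passed, with Acta1 at 159 ± 62.2 TPM (SD, n = 2), Myl1 at 16.5 ± 8.02 and Eno3 at 13.1 ± 5.88. In epidermis 4 of 13 passed, with Sbsn at 24.6 ± 9.55, Lgals7 at 10.9 ± 7.76, Dmkn at 7.49 ± 0.544 and Sfn at 5.66 ± 3.58. Of the 6 genes measured for mesothelium, which lines body cavities, 5 passed, with Wt1 at 75.6 ± 91.4 and Upk3b at 55.5 ± 33.1. All 17 clock genes passed (Nr1d1 171 ± 71.5, Dbp 54.9 ± 13.2, Tef 53.8 ± 3.27, Cry2 36.1 ± 9.09), as did 24 of 26 nuclear receptors (Pparg 150 ± 84.7, Nr1h2 123 ± 37.2, Nr1h3 122 ± 64.6) and 17 of 19 immediate early genes (Jund 134 ± 111, Dusp1 91.9 ± 64.7, Zfp36 66.2 ± 32.4, Jun 43.9 ± 23.8). All 10 heat shock genes and all 15 housekeeping genes passed, with Hspa8 at 2620 ± 1133, Hspb1 at 262 ± 43.2, Hsp90aa1 at 101 ± 47.3 and Hspd1 at 35.5 ± 4.06. Of the housekeeping genes, Actb was at 4146 ± 923, Gapdh at 3328 ± 135, Rpl13a at 2719 ± 1756 and Rplp0 at 1605 ± 1005. Among long noncoding RNAs 13 of 14 passed, with Neat1 at 706 ± 477, Meg3 at 400 ± 107, Malat1 at 385 ± 310 and Rian at 148 ± 15.7.

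**Figure D1:**
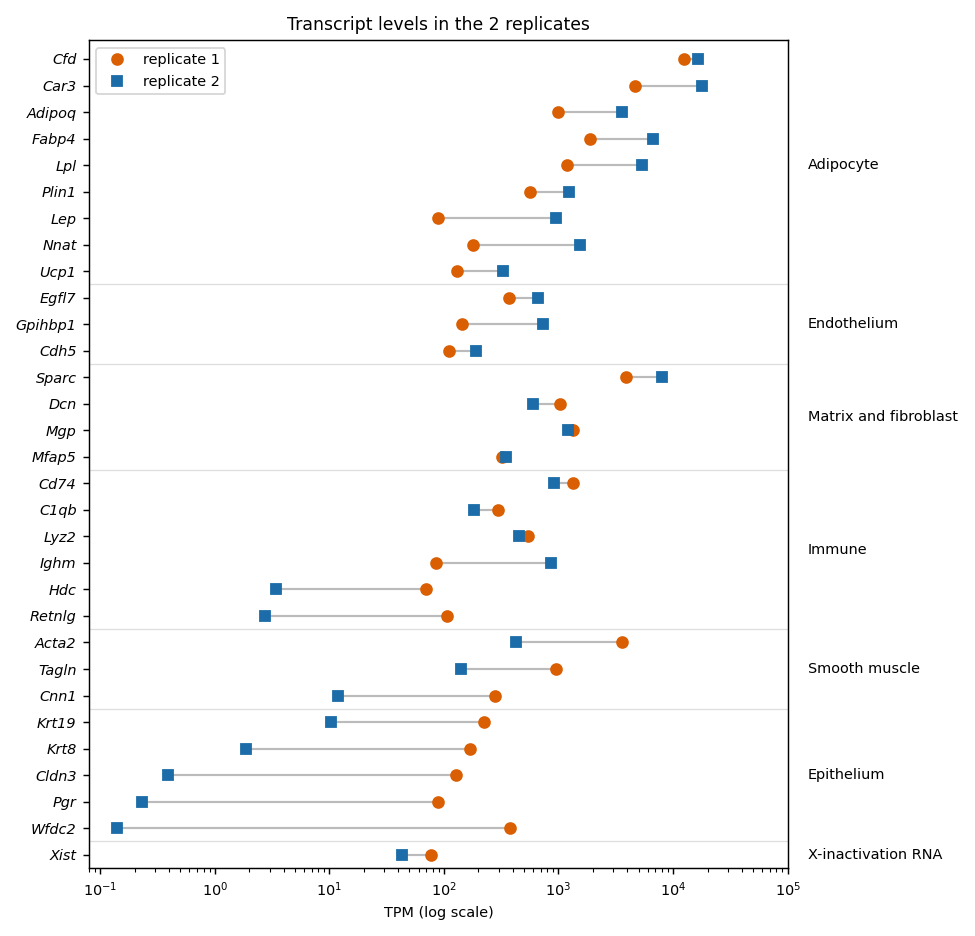
TPM (log axis) of 31 genes in replicate 1 (orange circles) and replicate 2 (blue squares), grouped by cell type, with a grey line joining the 2 libraries. Adipocyte genes were higher in replicate 2 (Lep 88.4 against 957 TPM), the epithelial genes were higher in replicate 1 (Krt8 169 against 1.87 TPM), and genes such as Mgp, Mfap5 and Lyz2 were close.

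Sex-linked transcripts were of the female kind in both libraries. Xist, the RNA that silences the second X chromosome of female cells, had 45378 counts (76.9 TPM) in replicate 1 and 25266 counts (43.4 TPM) in replicate 2. The 4 Y genes Ddx3y, Kdm5d, Eif2s3y and Uty together had 6 and 4 counts, which is 0.0218% and 0.0207% of the 27542 and 19359 counts of their X-linked counterparts Ddx3x, Kdm5c, Eif2s3x and Kdm6a. All 1569 annotated Y chromosome genes together had 11 and 15 counts. The labels describe the tissue as pooled from males and females.

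Between the replicates, with TMM scaling, all 18 white adipocyte genes were over 2-fold higher in replicate 2, with a median log2 ratio of 2.12. All 13 mitochondrial mRNAs were over 2-fold higher there too, with a median of 1.54. Conversely, 14 of 15 genes of mammary and glandular epithelium were over 2-fold higher in replicate 1, with a median of -5.86, as were 14 of 15 cell division genes, with a median of -2.48. Of the 24 genes on the epithelium list, 15 reached a TPM of 1 in replicate 1 and 4 in replicate 2. Its members Csn2 and Wap had 0 counts in both libraries and Elf5 had 59 and 1. The list therefore does not tell which epithelium was present. Of 13403 genes with a mean scaled count of at least 100, 3101 (23.1%) were over 2-fold apart, 1681 higher in replicate 1 and 1420 higher in replicate 2. The common biological coefficient of variation was 64.5%. Differences of over 8-fold were more often in the direction of replicate 1, with 468 genes against 54.

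Lep was 17.2-fold higher in replicate 2 (95% counting interval 16.8 to 17.5), Lpl 7.19-fold (7.14 to 7.24), Fabp4 5.91-fold (5.86 to 5.97), Car3 5.74-fold (5.71 to 5.76) and Adipoq 5.60-fold (5.54 to 5.66), whereas Cfd was 2.04-fold higher (2.04 to 2.05). The lipolysis list had 12 of 15 genes over 2-fold higher in replicate 2 (median log2 ratio 1.79), the adipokine list 12 of 21 (1.33) and fatty acid and triglyceride synthesis 10 of 19 (1.26). So were 8 of 16 thermogenic genes (1.33), Ucp1 by 3.97-fold (3.86 to 4.08). The deiodinase gene Dio2, chosen after its values were seen, was the 1 thermogenic gene over 2-fold higher in replicate 1, by 57.0-fold (49.4 to 66.0). Endothelial genes followed, with 11 of 15 (1.42) and Gpihbp1 at 8.05-fold (7.76 to 8.35), and then the nuclear respiratory chain with 5 of 25 (0.85). In the B cell list 3 of 13 genes were over 2-fold higher in replicate 2 (1.37), Ighm by 15.3-fold (14.8 to 15.8) and Ighd by 6.48-fold (5.10 to 8.32), and 10 were within the bound. Each of the 9 lists given here or above as higher in replicate 2, mitochondrial mRNAs included, stood above 99% of its matched random lists. These lists are not independent. The white adipocyte list shares Pnpla2, Lipe, Plin1 and Adrb3 with lipolysis, and Adipoq, Lep, Retn and Cfd with the adipokine list. The B cell list was no longer outside them over members with a mean count of at least 50 (0.28), nor was fatty acid and triglyceride synthesis by mean log2 ratio (0.97).

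In replicate 1, the epithelial keratin gene Krt8 was 58.1-fold higher (95% counting interval 48.9 to 69.5), the keratin gene Krt19 14.5-fold (13.3 to 15.8), the tight junction gene Cldn3 207-fold (131 to 350) and the progesterone receptor gene Pgr 265-fold (191 to 378). Mast cells had 6 of 7 genes over 2-fold higher (median log2 ratio -2.44), with Hdc at 14.2-fold (12.7 to 16.0) and Kit within the bound. Neutrophils had 7 of 10 (-2.17), with Retnlg at 25.2-fold (18.8 to 34.4). In mesothelium, the lining of body cavities, 4 of 6 genes were higher (-1.53), Wt1 by 8.69-fold (8.04 to 9.41). The mesothelial genes Upk3b (1.57-fold) and Msln (1.78-fold) were within the bound, and Krt19 is also on the glandular epithelium list. In smooth muscle and pericytes 7 of 14 were higher and 1 was lower (-1.20): Acta2 by 5.34-fold (5.27 to 5.40) and the contractile gene Cnn1, with 22803 against 1139 counts. Mcam was the opposite and was 2.59-fold higher in replicate 2 (2.54 to 2.64). RNAs without a long polyA tail were split, with 6 of 10 higher in replicate 1 and 2 in replicate 2 (-1.47), and Rn7sk was 4.03-fold higher in replicate 1 (3.98 to 4.08). With glandular epithelium and cell division, these were the 7 lists below the random lists, the highest percentile being 0.38, for mast cells. By mean log2 ratio (-0.88) the RNAs without a long polyA tail were not outside. A list of uterus genes, written after the first look at the data, was higher in replicate 1 together with these groups, smooth muscle included, by a median of 28.5-fold over 13 genes.

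The largest single ratios were on the side of replicate 1. A2m had 12347 counts against 1 (ratio 9272, 95% counting interval 1664 to 366245), Wfdc2 8458 against 4 (1588, 620 to 5829), Gpx2 1805 against 1, Stra6 8227 against 5, Vwa2 3033 against 2, Gdf7 2686 against 2, Wnt7a 2512 against 2, Foxl2os 3225 against 3, Calb1 2173 against 3, and Esrp1 1321 against 2. The collagen gene Col6a4 had 53535 against 57 (705, 544 to 931). Slc26a7 had 3766 counts against 0 and was at least 943-fold higher by the floor of 3 counts, with a lower 95% counting limit of 766. In the direction of replicate 2, Atp1a4 had 3 counts against 436 (ratio 194, 65.8 to 942), Mrgprg 2 against 259, Gm6311 30 against 2196, and Rnase2a 3 against 212. The airway secretory gene Scgb1a1 had 4 against 207, Gm10020 13 against 571, Sfrp5, an adipokine that binds Wnt proteins, 130 against 5534 (56.7, 47.6 to 68.0), Serpina1b 117 against 4095, 9030619P08Rik 9 against 287 and Slc5a7 8 against 255. Gm28048 had 0 against 259 and Gm3411 0 against 202, at least 115-fold and 89.7-fold higher by the same floor. Their lower 95% counting limits were 92.8 and 72.3.

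**Figure D2:**
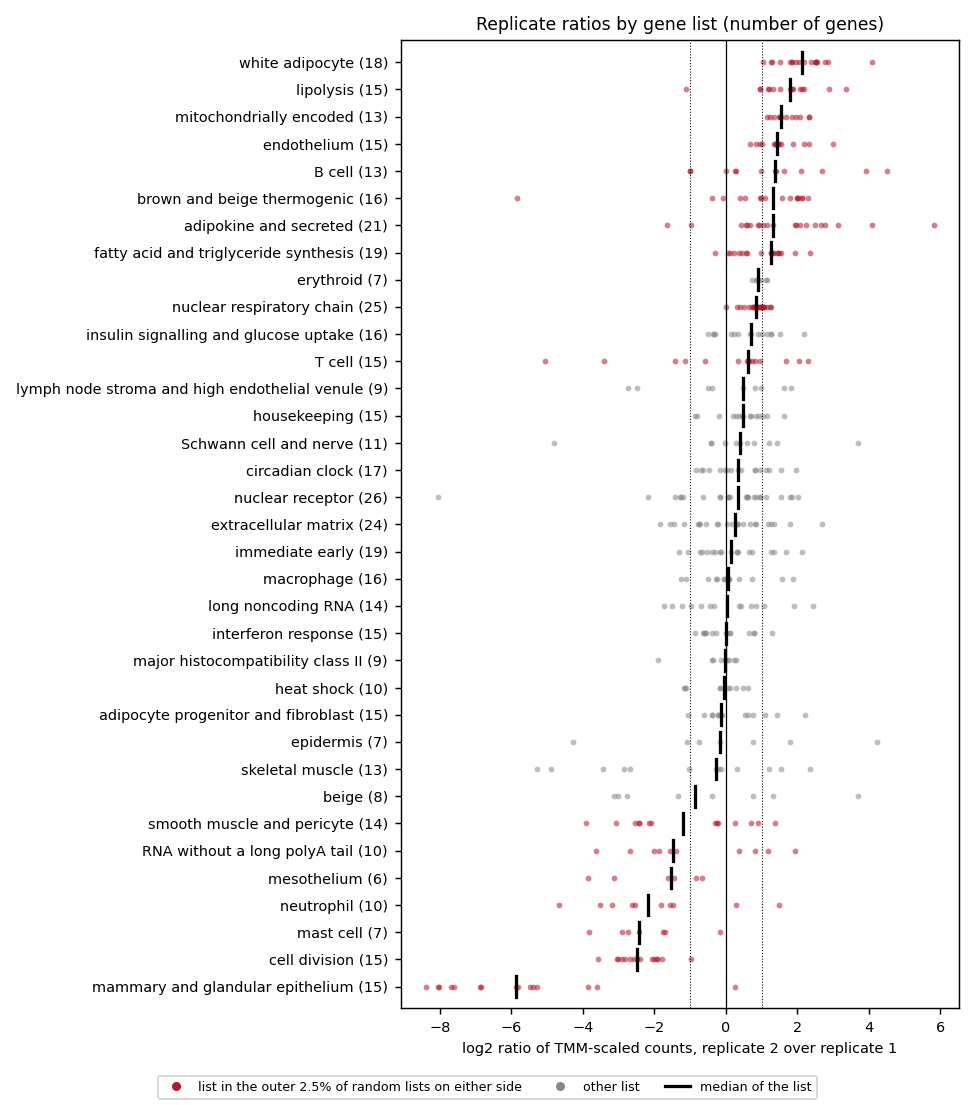
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1 (horizontal axis), of each gene with a mean scaled count of at least 10 (points) in the 35 lists compared (with the number of genes), with the list median as a black bar, a solid line at 0 and dotted lines at a 2-fold difference. Lists in the outer 2.5% of matched random lists on either side are red; medians run from -5.86 for glandular epithelium to 2.12 for white adipocytes.

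In the T cell list, 2 of 15 genes were over 2-fold higher in replicate 2 and 3 in replicate 1, the latter being its most abundant members Tcf7 (10.6-fold, 8.80 to 12.9), Lck (2.66-fold, 2.24 to 3.18) and Lef1 (33.5-fold, 22.9 to 51.1). Its median log2 ratio of 0.62 stood at the 98.9 percentile, but was -1.14 over the members with a mean count of at least 50, so no direction is given for this list. Fibroblasts and progenitors (median -0.14, 3 of 15 over 2-fold apart), heat shock (-0.05, 2 of 10), class II (-0.03, 1 of 9), interferon response (0.01, 1 of 15), macrophages (0.06, 3 of 16), long noncoding RNA (0.02, 6 of 14), immediate early genes (0.16, 5 of 19), matrix (0.25, 9 of 24), nuclear receptors (0.34, 11 of 26), clock (0.35, 3 of 17), nerve (0.41, 3 of 11), housekeeping (0.47, 2 of 15), lymph node stroma (0.48, 3 of 9), insulin and glucose uptake (0.70, 5 of 16) and erythroid genes (0.90, 2 of 7) lay inside the random lists. So did beige markers (-0.86, 6 of 8), skeletal muscle (-0.28, 7 of 13) and epidermis (-0.16, 3 of 7). Classical brown markers had 3 genes to compare, too few to place (-1.25). The female-specific list is Xist alone, 1.35-fold higher in replicate 1 (1.33 to 1.37), and no Y gene had enough counts.

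These ratios compare the 2 libraries and have no replicate check. Scaling by the spike-in total moved every log2 ratio by -0.46 and scaling by total count by -0.51, so each ratio is read relative to that shift. The share of over 2-fold genes that were higher in replicate 1 went from 54.2% to 81.1% and 83.5%. Genes over 2-fold higher in replicate 2 fell from 1420 to 656 and 592. The counts of over 2-fold genes in each list are with TMM scaling and depend on it too. Among genes with a mean count of at least 500 the majority turned, with 895 higher in replicate 1 and 1138 higher in replicate 2. The 39 spike-ins with a mean count of at least 100 had an SD of 0.20 in their log2 ratio and none was over 2-fold apart, against an SD of 1.46 for the 13404 genes in their count range. The robust SD, which gives the tails less weight, was 0.18 for the spike-ins and 0.80 for those genes. Across the 12759 genes at a TPM of at least 1 in both libraries, Pearson's r of log2 TPM was 0.895 and Spearman's rho of TPM was 0.889; genes are not independent replicates.

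Isoform use was read for 15 genes from the share of a gene's TPM that each transcript took. Pparg, the regulator of adipocyte formation (GRCm38 chromosome 6, 115422066 to 115490399 for Pparg-201), was expressed mainly as Pparg-201, which encodes 505 residues, at 94.6 ± 1.94% (SD, n = 2), with the 475-residue Pparg-202 at 5.38 ± 1.94%. The pyruvate kinase gene Pkm had 78.0 ± 6.55% as Pkm-201, whose own internal exon lies at chromosome 9, 59675568 to 59675734, and 22.0 ± 6.55% as Pkm-202, with the upstream exon of the same exclusive pair at 59675029 to 59675195; these are the M2 and M1 forms. Adipoq-201 took 99.5 ± 0.163%, Lep-201 98.4 ± 1.10%, Lpin1-201 91.5% and 93.6% in replicates 1 and 2, Slc2a4-201 86.2 ± 3.08% and Nnat-202 78.0 ± 3.14% of their genes, and Insr-201 took 63.9 ± 7.91% beside a transcript with a retained intron. Cd36 was divided over Cd36-204 (41.1 ± 0.276%) and Cd36-202 (36.1 ± 1.12%), and the leading transcripts of Lmna, Srebf1, Vegfa, Fn1 and Mlxipl by the mean of the replicates were Lmna-201 (33.1 ± 0.983%), Srebf1-203 (31.5 ± 7.51%), Vegfa-203 (29.8 ± 2.90%), Fn1-202 (29.6 ± 10.5%) and Mlxipl-201 (28.5 ± 0.113%).

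The same transcript led in both replicates for 10 of the 15 genes. Lmna-203 led in replicate 2 (35.8% against 33.8% for Lmna-201), Srebf1-201 in replicate 1 (29.0% against 26.15% for Srebf1-203) and Mlxipl-208 in replicate 2 (30.2% against 28.4% for Mlxipl-201). In the tropomyosin gene Tpm1, Tpm1-211 took 1.24% in replicate 1 and 25.3% in replicate 2, while Tpm1-215 took 43.0% and 24.7%; the gene itself was higher in replicate 1, at 338 against 45.8 TPM. In Fn1, Fn1-214 led in replicate 1 with 24.1% and took 7.14% in replicate 2. By share of expected counts the same transcript led in 13 of the 15 genes, and some leaders and shares were others. Vegfa-203 took 7.52% and 9.17% of counts in replicates 1 and 2, below Vegfa-202 at 41.4% and 37.0%. Fn1-202, a retained-intron transcript, took 13.9% and 24.2%, below Fn1-214 in replicate 1 (31.1%) and Fn1-203 in replicate 2 (45.1%). The shares of Lmna-201 and Mlxipl-201 were 56.4% and 47.6% of counts on average.

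The junction table, which pools both libraries on build mm9, listed 480876 splice junctions. The most used was on chromosome 10, from 79354358 to 79354447, with 296297 reads, followed by an intron on chromosome 19, from 44472609 to 44474631, with 272541 reads; these positions were not matched to genes here because the annotation used is of the other build. Of all junctions, 176997 (36.8%) had reads under both of the numbers in their name and these carried 98.6% of the reads, while 220472 junctions (45.8%) had 1 read. Of 58999 junctions with at least 100 reads, 235 had reads under 1 of these numbers alone, 221 of them under the first and 14 under the second. The Y chromosome had 23 junctions with 37 reads in all.

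The contig table listed 747944 transcribed stretches covering 278 Mb, with a median length of 206 bases, 381052 on the plus strand and 366892 on the minus strand. The 301603 contigs with a score of at most 0.1 covered 208 Mb and held 99.1% of the read bases, and the 100 contigs with the most bases held 21.7%. The mitochondrial genome held 3.05% of the read bases in 6 contigs. The Y chromosome had 30 contigs, with a highest level of 2.40, against 19352 on the X chromosome, with a highest level of 2540.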

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

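ERCC spike-in RNAs, which are outside the tissue measurement, took 2.06% of the counts on average, 2.10% in replicate 1 and 2.02% in replicate 2, far above the 3 counts that a count of 0 allows.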

How the results depend on the processing

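No paired analysis was possible because the series has a single group. The number of expressed genes stayed within 1.5 times of 12759 under all 8 alternatives, and from 13076 to 14762 with either replicate left out. The 10 most abundant genes held from 12.8% to 23.1% of TPM and the 100 most abundant from 33.7% to 46.5% with a replicate left out; of expected counts they held 11.9% and 28.1%, and the cause was not tested. The median log2 ratio of -0.00 moved to -0.52 with total count, -0.46 with spike-in scaling (chosen after seeing the data for the counts of genes and lists), -0.62 with TPM and a pseudocount of 0.1, and -0.47 with a pseudocount of 1. Genes over 2-fold apart numbered 2033 at a mean count of at least 500, where fewer genes qualify and 44.0% were higher in replicate 1, and from 3103 to 4390 otherwise, with DESeq2 size factors giving the lowest. All 17 lists outside the random lists remained so with TPM and with the farthest member left out, where nuclear receptors made 18; 15 remained with a minimum mean count of 50 and 14 by mean log2 ratio. DESeq2 and spike-in scaling shift all genes alike and are no test of these 17. The T cell median of 0.62 turned to -1.14 at a mean count of 50, which leaves out its low members, and its mean was -0.0570, where the cause was not tested. B cell and T cell were lost at 50, and RNA without a long polyA tail, T cell and fatty acid and triglyceride synthesis by the mean. The coefficient of variation stayed from 0.584 to 0.665. Junctions fell from 480876 to 146068 and 86718 at scores of at most 0.1 and 0.01 and to 167152 at 5 reads, and contigs from 747944 to 301603, 129258 and, at 200 bases, 380602, as filters remove entries. For named gene ratios, 940 combinations of gene and setting kept the call of over 2-fold or its absence, 152 did not, and no called gene changed direction.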

Other observations

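Tests of mammary gland, of a tissue as the whole cause, depth, Y gene reads and cell type shares were chosen after the results were seen; the 9 other tissue lists and the spike-in scaling test were written before their values were seen. The following genes were also chosen after their values were seen. Ribosomal protein genes had a ratio on the side of replicate 1 for 76 of 80 genes, of which 7 were over 2-fold higher, and their median log2 ratio was -0.57 with TMM and -1.02 with spike-in scaling. The estrogen receptor gene Esr1 had 16018 counts in replicate 1 and 2653 in replicate 2, a ratio of 4.53 after TMM scaling (95% counting interval 4.35 to 4.73). The fibrillar collagen genes Col1a1 and Col1a2 were 2.23-fold and 3.57-fold higher in replicate 1, whereas Sparc was 3.48-fold higher in replicate 2.

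Depot genes were also uneven. In the visceral depot list 8 of 9 genes in replicate 1 and 7 in replicate 2 reached a TPM of 1, with Wt1 at 7937 and 686 counts and Tcf21 at 5252 and 1062 counts, while Nr2f1 (1.54-fold), Hoxa5 (1.89-fold) and Gata4 (2.96-fold) were on the side of replicate 2; 4 of 9 were over 2-fold higher in replicate 1 and 5 met that rule in neither direction (median log2 ratio -0.83, percentile 0.885, 6 of the 9 genes shared with the lists fixed earlier). In the subcutaneous depot list 3 of 6 reached a TPM of 1 in each, and 3 of the 4 compared genes were higher in replicate 2, Hoxc10 by 4.71-fold (4.20 to 5.29), Hoxc9 by 2.47-fold (2.11 to 2.91) and Shox2, with 3 and 29 counts, by 12.9-fold (3.99 to 66.0), against Sfrp2 at 163 and 45.8 TPM (percentile 99.9, 2 genes shared). The remaining members were near the floor in both replicates, Tbx15 with 5 and 7 counts and En1 with 3 and 10. Which depot the tissue came from was not tested. Replicate 2 held low counts of genes of distant organs: Svs5 and Svs4, of the seminal vesicle, had 107 and 41 counts against 3 and 1 in replicate 1, and Sftpc, of the lung, had 62 against 0.

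The epithelial genes far higher in replicate 1 may come from tissue beside the fat pad, a hypothesis found and tested on the same data. A tissue was kept with at least 70% of its list at a TPM of 1 in replicate 1 and a median of at least 8-fold. A share under 30% argued against it. As the whole cause, a tissue was argued against when its median lay over 1.5 SD from that of the glandular epithelium list. Of a uterus list, 13 of 15 genes (86.7%) reached a TPM of 1 in replicate 1 and 6 in replicate 2, with a median of 28.5-fold, led by Sox17 (201 and 66.4 TPM), Hoxa10 (164 and 14.2) and Msx1 (125 and 2.80), while Prss28 and Prss29 had 0 counts; of bladder urothelium, 4 of 4 (100%) did and 2 in replicate 2, with a median of 12.4-fold, led by Upk1a (781 and 107 counts) and Upk1b (1014 and 332). Kidney (10%), intestine (28.6%), prostate and seminal vesicle (0%) and lung (16.7%) lists are argued against, being mostly below a TPM of 1, and the total count of replicate 1 was 0.933 times that of replicate 2, against depth. As the whole cause, ovary (30%, 1.29-fold) and liver (66.7%, 2.64-fold, with Alb and Cyp2e1 over 2-fold higher in replicate 2) are argued against by list medians 4.06 and 1.93 SD from that of the glandular epithelium list, whereas uterus, bladder urothelium and ciliated oviduct (33.3%, 1.40-fold, 3 genes) lay 0.528, 1.13 and 1.25 SD from it, and mammary gland (4 of 10 genes, 40%, percentile 1.18, 4.85-fold over 4 genes that go both ways, Krt5 with 208 and 4 counts, Elf5 with 59 and 1, Prlr with 518 and 1121) 0.949 SD. The gaps were divided by each list's own SD, so a list whose members disagree stays open more easily. Ciliated oviduct had nearly the gap of ovary (5.38 against 5.50 on the log2 scale) but an SD of 4.31 against 1.36. Its genes went both ways, Foxj1 with 166 and 3 counts, Ovgp1 with 145 and 78 and Tekt1 with 12 and 84. The SD of mammary gland was 3.77, so the rule decides on neither tissue. Uterus and bladder urothelium stay open as candidate sources, and ciliated oviduct and mammary gland are undecided. As the whole cause, uterus stays open, while bladder urothelium is undecided. Its 4 genes ranged from 2.29-fold (Upk1b) to 41.8-fold (Upk3a) higher in replicate 1. In the lists fixed earlier are 8 of the 10 mammary gland genes and none of the other candidates' genes. Neither a difference between the animals nor a shared source of the smooth muscle, mast cell and cell division genes was tested.

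Y transcripts were near 0 in tissue labelled as mixed sex, while the male-organ genes Svs5 and Svs4 had 107 and 41 counts in replicate 2. These low counts were seen in that library beside 62 counts of the lung gene Sftpc, and their source was not tested. Y reads assigned to X counterparts by the counting program are argued against by the separate junction table, where 0.881 of 1000000 reads lay on the Y chromosome. The 4 Y genes had 0.0218% and 0.0207% of the counts of their X-linked counterparts in replicates 1 and 2. This argues against a sizable share of RNA from male cells in either library. How the animals were pooled was not tested.

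For adipocyte genes lower in replicate 1, the median log2 ratio of the white adipocyte list was 2.12 with TMM and 1.66 with spike-in scaling. Spike-in scaling moved every ratio by -0.46, nearly as total count did (-0.51). It therefore cannot decide whether a few abundant genes set the scale. Any such scale shifts all genes alike, and the list stood above its matched random lists (percentile 100). Its difference from other genes thus does not rest on the scale. A lower share of adipocytes with all other cell types in fixed proportions is argued against as the whole cause. The medians of 11 other cell type lists lay up to 7.28 apart on the log2 scale, 3.22 times their largest SD. This gap lies between endothelium (1.42) and glandular epithelium (-5.86), which also has that SD. It thus rests on the epithelial genes described above and does not test proportions among the cell types of the fat pad alone. A lower share together with other tissue in replicate 1 stays open.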
